A study of Homo sapiens with 2 samples.

How the data were processed

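Total RNA from the human lung adenocarcinoma cell line CL1-5, a highly invasive non-small-cell lung cancer line, was hybridised as biotin-labelled cRNA to Affymetrix Human Genome U133 Plus 2.0 arrays, per the labels' protocols. One culture was exposed for 24 h to 0.11 µM analogue 3, an iodo-, tripropyl- and methoxy-substituted analogue of the natural product desmosdumotin C, and the other to the solvent DMSO. There was 1 array per group, so no difference has a replicate check and no p-value is given for any gene or gene list.

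The deposited table holds 1 intensity per probe set and array, on a linear scale, for 54675 probe sets. GCRMA, a background correction that uses probe sequence followed by quantile normalization and summarisation, is named in the submitters' processing notes, with its version not given in the sources used here. The intensity values the authors deposited had a median of 1 on each array, so a further division by the array median was read from the values; no label states it. The lowest value on either array was 0.117, and the highest was 3117 on the analogue 3 array and 3078 on the DMSO array. When each column was sorted, the 2 columns differed by at most 0.14 on the log2 scale. All intensities below are therefore multiples of the array median, and an unstated scaling step cannot be undone.

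Probe sets were named from GEO's platform annotation, in which 41097 probe sets carried exactly 1 gene symbol and 1801 carried several. A further 11777 probe sets were not listed there and stay unnamed here. Of the 62 control probe sets, 6 carried a gene symbol there (ACTB or GAPDH) and 56 did not. Of the single-gene probe sets, 41043 matched the RefSeq gene table (GRCh38.p14) by gene number, and their symbols were already current. No genome was used, so no coordinates are given. Each gene was represented by its single-gene probe set with the highest mean log2 intensity.

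Values were log2-transformed, values under log2 5 (32 times the array median) were raised to that floor, and the difference analogue 3 minus DMSO was taken. A gene counted as measured when at least 1 array reached the floor, and as different when the floored difference was at least 2-fold. This floor was fixed before the data were examined, when the values were expected on the usual GCRMA log2 scale. On the deposited scale it is strict, since 13.1% of probe sets reached it on the analogue 3 array and 13.4% on the DMSO array. Where 1 array lay under the floor, the fold is a lower bound against the floor and is given as "at least".

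Also before the data were examined, 37 gene lists were fixed: cell cycle, stress, metabolic, signalling and housekeeping groups, and markers of other cell types. For each list the median floored log2 difference over its measured members was set against 10000 random lists of the same size matched on mean level in 20 bins. The resulting percentile describes these 2 arrays only. Lists can share genes. The genes named were the 12 largest differences each way among genes at or above the floor on both arrays whose other probe sets had the same sign; the 5 largest bounds each way; up to 4 members of each list; and 17 genes fixed by name (cell cycle genes, MYC and tubulin genes). A gene also passed this sign rule where it had no other probe set at or above the floor on both arrays. Of the 12 genes each way, only RRM2 and MCM4 had such a probe set. Genes of the lists with medians near 0 were named in part. Uncharacterised loci and pseudogenes were passed over. Other genes named are members of those lists chosen after their values were seen.

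The technical error that 2 arrays can show is the spread between different probe sets of a gene. Among 1127 genes with at least 2 probe sets above the floor on both arrays, the log2 differences of the brightest and the next probe set correlated across genes with r = 0.86, and the SD of 1 probe set was 0.17. Genes are not independent replicates, and this spread leaves out culture, RNA and hybridisation error. The number of arrays limits the precision of every value.

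The procedure was tested on simulated data made from the real mean levels with this SD as noise and a seeded set of changed genes, among 4758 measured genes. It called 50 of 50 genes changed 4-fold, 47 of 50 changed 3-fold, 43 of 50 changed 2.5-fold and 2 of 50 changed 1.5-fold, and 0 of 4558 unchanged genes. Probe-set noise was the only noise simulated. It is small against the 2-fold threshold, so the 0 was fixed in advance and gives no real rate of false calls. Of random lists drawn from the simulated genes, 6.5% fell outside percentiles 2.5 to 97.5.

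Alternatives were a floor of log2 4 or 7, no floor, centring on the median difference, removal of a loess trend on level (span 0.3), quantile normalization of the 2 arrays, the median of a gene's probe sets, omission of probe sets ending in _s_at or _x_at (which can share sequence with other transcripts), and thresholds of 1.5-fold and 3-fold. Floors of log2 1 and 3 were added after seeing the data, because of the deposited scale. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.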

Results

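The data comprised 2 whole-transcriptome arrays of CL1-5 lung adenocarcinoma cells, 1 after 24 h with 0.11 µM analogue 3 and 1 after 24 h with DMSO. The dose equals the concentration that the submitters give as the median effective dose of the compound in these cells. The comparison asked which transcripts differed between the treated and the control culture. Of the genes named on the array, 5050 were measured and 4288 of them lay at or above the floor on both arrays. Across the measured genes, log2 levels on the 2 arrays correlated with r = 0.91, and 81.4% of genes differed by less than 1.5-fold. The median log2 difference was -0.01.

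Transcripts of DNA replication and of mitosis were higher with analogue 3, and transcripts of the amino acid and integrated stress response and of the interferon response were lower. In all, 175 genes (3.47% of those measured) were at least 2-fold higher and 135 (2.67%) were at least 2-fold lower. Which direction held more genes depended on the floor, since 475 were higher and 724 lower with no floor. Of the 175, 85 belonged to at least 1 of 8 fixed lists for cell cycle, chromosome and DNA repair genes. Of the 135, 23 belonged to the ATF4 or interferon lists. With 1 array per group there was no test of these differences. Among genes that were at least 2-fold different in their brightest probe set, 42 of 43 with a second probe set above the floor had the same sign there, and 37 were also at least 2-fold different.

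**Figure D1:**
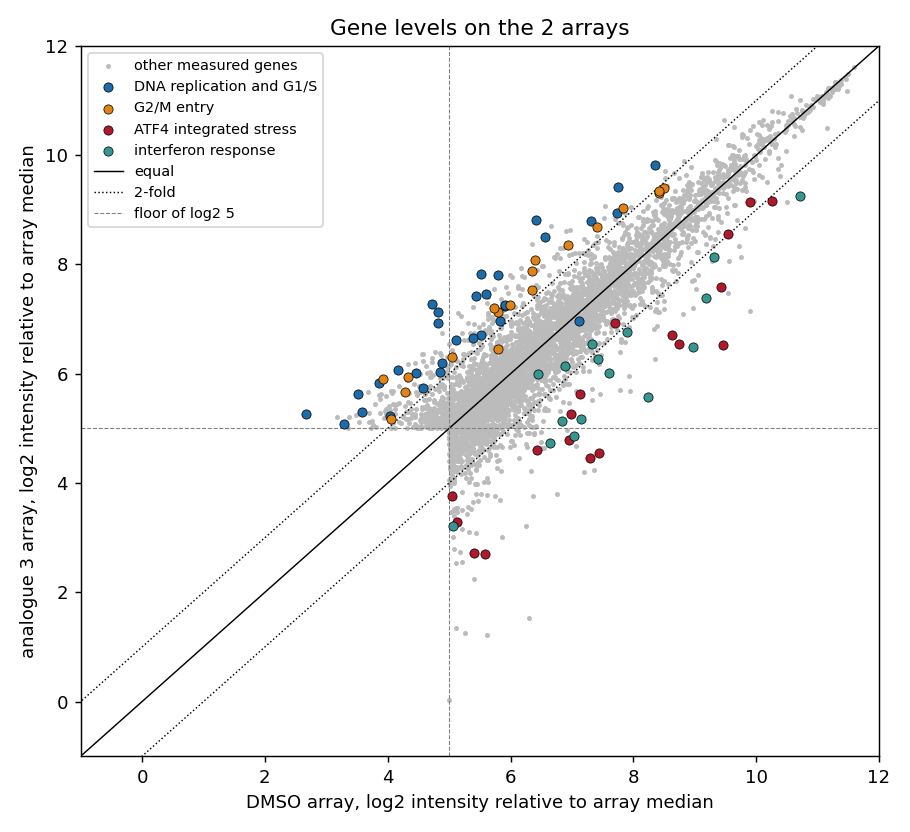
Log2 intensity relative to the array median on the DMSO array (x axis) against the analogue 3 array (y axis), 1 point per measured gene, with members of 4 fixed lists coloured, dotted lines at 2-fold and dashed lines at the floor of log2 5. Replication and G2/M genes lie mostly above the diagonal, and all 34 measured genes of the ATF4 and interferon lists lie below it.

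The largest difference upward among genes measured on both arrays was in RRM2, a subunit of ribonucleotide reductase, which makes deoxyribonucleotides. Its intensity was 449.9 with analogue 3 and 85.3 with DMSO, a 5.28-fold difference, with a log2 difference of 2.40, and of 2.06 in its other probe set. GINS1, a subunit of the replicative helicase complex, was 4.98-fold higher. The mitotic kinesin KIF20A was 4.13-fold higher, and the kinetochore gene SPC25 was 4.11-fold higher. The helicase subunits MCM3, MCM4 and MCM6 were 4.02-, 3.96- and 3.62-fold higher. The PCNA-binding factor PCLAF, the flap endonuclease FEN1, the spindle protein gene DLGAP5 and the checkpoint kinase gene BUB1 were 3.97-, 3.80-, 3.63- and 3.55-fold higher. ID3, an inhibitor of basic helix-loop-helix transcription factors, was 3.90-fold higher and was the only 1 of these 12 genes outside replication and mitosis. Where the DMSO array lay under the floor, GINS2 was at least 4.83-fold higher, UHRF1 at least 4.37-fold, MCM5 at least 3.79-fold, HELLS at least 3.34-fold and the HSP90 co-chaperone FKBP4 at least 2.93-fold.

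The DNA replication and G1/S list was higher with a median log2 difference of 1.25 over 31 measured members (quartiles 0.92 and 1.89), or 2.39-fold. Of these, 23 were at least 2-fold higher, none was 2-fold lower and 30 lay above 0. The median lay above all 10000 random lists, and was 0.81 over 15 members with a floor of log2 7. CCNE2, the G1/S cyclin, was measured at 49.3 against 11.5, a bound of at least 1.54-fold higher. Of the G1 cyclin and CDK inhibitor list, CDK2 was at least 2.59-fold higher, and CCND1 and CCND3 were 1.66- and 1.94-fold higher. For CCND1 the log2 difference was 0.73, and 0.37 in its other probe set. CDKN1A, the gene of the CDK inhibitor p21, was at least 1.78-fold lower, at 25.8 against 57.0. The median of that list was 0.04 over 9 members, at percentile 67.6. It was 0.18 over 13 members, at percentile 93.3, with a floor of log2 1, turned to -0.01 after quantile normalization, and ran from -0.07 to 0.37 over all alternatives. Replication-dependent histone genes were sparsely measured, with a median of -0.22 over 5 members, which turned to 0.06 over 9 members with a floor of log2 1. Of these genes, H4C8 was 8.60 against 40.2, a bound of at least 1.25-fold lower.

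Mitotic lists were higher by a similar amount. The mitotic spindle, motor and centrosome list had a median of 1.23 over 27 members, 19 of them at least 2-fold higher and all above 0. The G2/M entry list had a median of 1.19 over 18 members, 10 of them at least 2-fold higher and all above 0. In that list CDK1, the main mitotic kinase, was 2.89-fold higher (log2 1.53, with 1.49 and 1.64 in its other probe sets). Its partners CCNB1 and CCNA2 were 2.30- and 2.51-fold higher, AURKA was 2.69-fold higher, PBK 3.24-fold and GTSE1 2.75-fold. For CCNB1 the log2 difference was 1.20, and 0.82 in its other probe set, which is under 2-fold. PLK1 was under the floor on both arrays, at 9.82 with analogue 3 and 2.92 with DMSO. The kinetochore and centromere list had a median of 1.17 over 20 members, 14 of them at least 2-fold higher and all above 0, with CENPW 3.51-fold, ZWINT 3.43-fold and CENPM at least 2.58-fold higher. Each of these medians lay above all 10000 random lists. With a floor of log2 7 they fell to 0.45 (spindle, 12 members), 0.90 (G2/M, 12 members) and 0.94 (kinetochore, 7 members).

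The spindle assembly checkpoint list, whose products delay anaphase until chromosomes are attached, had a median log2 difference of 1.11 over 16 members, or 2.16-fold, above all 10000 random lists. With a floor of log2 7 it fell to 0.52 over 10 members. Of its members, 9 were at least 2-fold higher, 6 had smaller differences or smaller bounds, and 1 was at least 2-fold lower. BUB1B, TRIP13 and MAD2L1 were 3.19-, 3.18- and 3.17-fold higher, AURKB was 2.28-fold higher, the kinase gene TTK at least 2.21-fold and CDC20, the anaphase-promoting complex activator, 2.12-fold. MAD1L1, the binding partner of the MAD2L1 product, was the member lower, at 52.7 against 159.9 (log2 -1.60), and was singled out after its values were seen. The list of the anaphase-promoting complex and its regulators had a median of 0.24 over 15 members, at percentile 95.4, and of 0.60 over 10 members with the median of each gene's probe sets. The ubiquitin-conjugating enzyme gene UBE2C was 2.29-fold higher and PTTG1, which encodes securin, 2.09-fold. ESPL1, the separase gene, was at least 1.85-fold higher.

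Related chromosome and microtubule lists were higher as well. Cohesin and condensin genes had a median of 0.48 over 16 members (0.72 over 19 with a floor of log2 1), with NCAPG 2.81-fold higher, and DNA repair genes a median of 0.99 over 13 members, 6 of them at least 2-fold higher, among them RAD51AP1 (3.06-fold) and H2AX (2.75-fold). Both medians lay above all 10000 random lists. Tubulin genes had a median of 0.58 over 11 members, at percentile 99.99, of which 9 lay above 0. TUBG1, the centrosomal gamma-tubulin gene, was 2.42-fold higher, TUBB 1.92-fold, TUBB3 1.84-fold and TUBA1B 1.45-fold. TUBE1, epsilon-tubulin, was at least 2.09-fold lower. Tubulin genes are near-identical in sequence, so values of the x_at probe sets that represent TUBB, TUBB3 and TUBA1B are uncertain between family members.

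**Figure D2:**
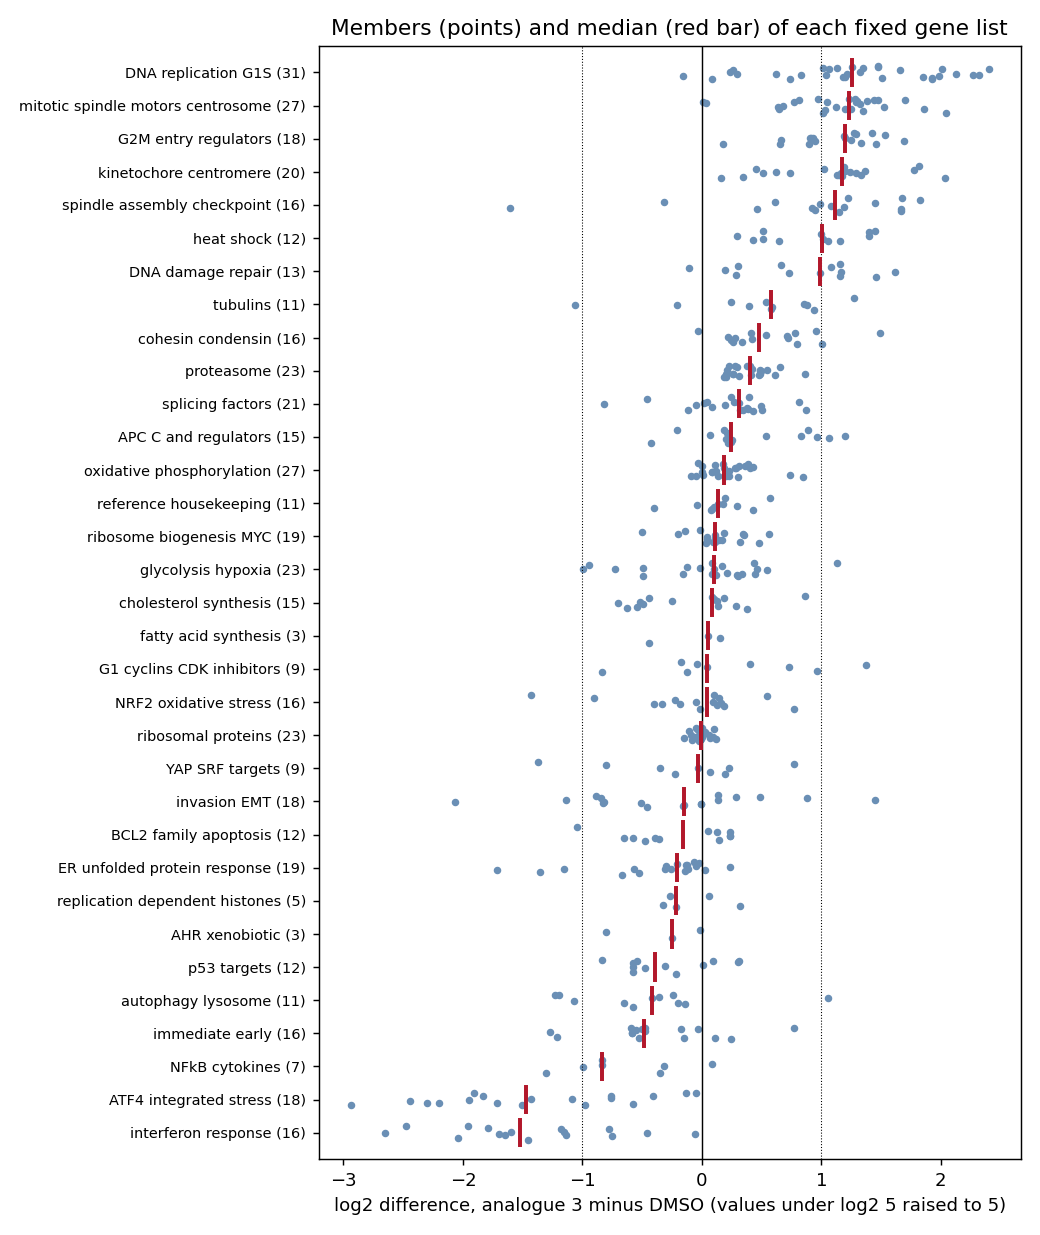
Log2 difference, analogue 3 minus DMSO, with values under log2 5 raised to 5 (x axis), for the measured members (points) and median (red bar) of each fixed gene list with at least 3 measured members; the number measured is in brackets and dotted lines mark 2-fold. Medians run from -1.53 in the interferon list to 1.25 in the replication list.

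The integrated stress list, made of ATF4 and genes it activates on amino acid shortage or endoplasmic reticulum stress, was lower with a median of -1.47 over 18 members (quartiles -1.94 and -0.76), or 2.77-fold. All 18 lay below 0, 11 were at least 2-fold lower, and the median lay below all 10000 random lists. ASNS, asparagine synthetase, had the largest difference downward among genes measured on both arrays, at 91.6 against 703.6, or 7.68-fold. The pseudokinase gene TRIB3 was 4.60-fold lower, the mTORC1 inhibitor gene DDIT4 3.76-fold and the serine synthesis enzyme gene PSAT1 3.56-fold. The transcription factor gene DDIT3 was at least 5.45-fold lower, and PHGDH, the first enzyme of serine synthesis, at least 4.92-fold. Outside the list, the gluconeogenic enzyme gene PCK2 and NIBAN1 were at least 5.11- and 5.39-fold lower. ATF4 itself was lower by 1.09 on the log2 scale, at 572.6 against 1220.

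The endoplasmic reticulum unfolded protein response list had a median of -0.21 over 19 members, at percentile 2.46 (-0.07 over 11 members with the median of each gene's probe sets), with 17 below 0 and 3 at least 2-fold lower. These were HERPUD1 (3.28-fold), HSPA5, the main chaperone of the reticulum (2.56-fold), and XBP1 (2.23-fold).

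The interferon response list had a median of -1.53 over 16 members (quartiles -1.83 and -1.05), or 2.88-fold lower, below all 10000 random lists. All 16 lay below 0 and 12 were at least 2-fold lower. The antiviral genes MX1, IFIT3 and OAS1 were 6.29-, 5.55- and 3.90-fold lower, and IFIH1, a cytoplasmic RNA sensor gene, at least 4.11-fold. Outside the list, the interferon-inducible gene IFI35 was 3.95-fold lower and CMPK2 at least 4.59-fold. Marker genes of leukocytes, fibroblasts, endothelium and differentiated lung epithelium were all under the floor on both arrays, and the highest leukocyte marker was CD3D at 1.17 with analogue 3 and LCP1 at 1.25 with DMSO. The highest fibroblast marker was COL1A1 at 5.50 and 3.93, and the highest endothelial marker PECAM1 at 15.7 and 11.4. Of the lung epithelial markers, MUC5AC was highest with analogue 3 at 4.53 and SFTPB with DMSO at 3.54.

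Several genes outside these lists were also lower. PAEP, which encodes the secreted protein glycodelin, was 6.79-fold lower, at 141.1 against 958.7. BEX2 was 4.81-fold lower, WDR45 4.24-fold and the uridine phosphorylase gene UPP1 4.23-fold. The interstitial collagenase gene MMP1 was 4.18-fold lower, at 178.9 against 747.6. The invasion and epithelial-mesenchymal list to which it belongs had a median of -0.15 over 18 members, at percentile 5.73, and ran from -0.26 to 0.06 over the alternatives, turning sign with the median of each gene's probe sets. In that list the laminin gene LAMB3 differed by -1.14 on the log2 scale and the integrin gene ITGA2 was 1.85-fold lower, while TGFBI was 2.73-fold higher. The NF-κB and cytokine list had a median of -0.84 over 7 members, at percentile 0.005 (-0.49 over 18 members, at percentile 0.16, with a floor of log2 1), with IL1A 2.46-fold lower and IL6 and IL1B at least 1.79- and 1.78-fold. Immediate early genes had a median of -0.49 over 16 members, below all 10000 random lists. JUND and KLF4 were 2.42- and 2.32-fold lower, IER2 was 1.51-fold and MYC 1.42-fold lower, and CCN1 was 1.71-fold higher.

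**Figure D3:**
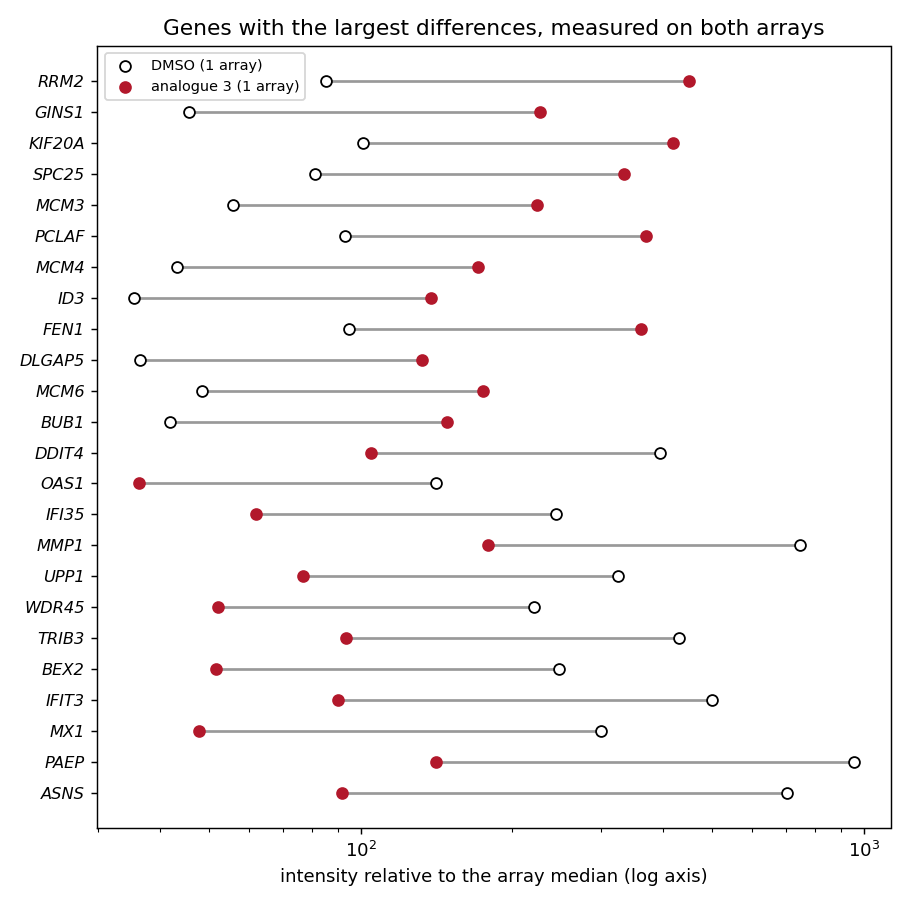
Intensity relative to the array median on a log axis for the 12 genes furthest higher and the 12 furthest lower among those at or above the floor on both arrays, with the DMSO array as open and the analogue 3 array as filled circles (1 array each). RRM2 stands at 85.3 and 449.9, and ASNS at 703.6 and 91.6.

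Heat shock chaperone genes were higher, with a median of 1.01 over 12 members, 6 of them at least 2-fold higher and all above 0, above all 10000 random lists. CHORDC1 was 2.72-fold higher, DNAJB1 at least 2.64-fold, HSPH1 2.63-fold and the mitochondrial co-chaperonin gene HSPE1 2.23-fold. Proteasome subunits were higher by a smaller amount, with a median of 0.40 and all 23 members above 0, among them PSMD1 (1.81-fold) and PSMD11 (1.57-fold). Splicing factors had a median of 0.31 over 21 members, at percentile 99.7, and of 0.14 over 11 members with the median of each gene's probe sets. Their largest member, HNRNPA2B1, was 1.83-fold higher in its brightest probe set and differed by -0.25 on the log2 scale in its other probe set. SRSF7 was 1.75-fold higher in its brightest probe set and differed by 0.21 on the log2 scale in its other probe set. SRSF6 was 1.76-fold lower.

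The p53 target list had a median of -0.39 over 12 members, at percentile 0.37, with 8 below 0 and 4 above. Those above were CCNG1 and TRIAP1 (log2 0.31 each), MDM2 (0.09) and TIGAR (0.01). With a floor of log2 1, an alternative added after seeing the data, the median was -0.20 over 22 members, at percentile 6.57, with 5 members at least 2-fold lower and 1 higher. SESN2, a stress-induced gene that is also in the ATF4 list, was 6.47 with analogue 3 and 47.8 with DMSO. Its bound was at least 1.49-fold lower. PMAIP1 and TNFRSF10B, both genes of cell death, were each 1.49-fold lower. The BCL2 family and caspase list had a median of -0.16 over 12 members, at percentile 12.5, and of -0.36 over 21 members, at percentile 0.52, with a floor of log2 1. The caspase inhibitor gene XIAP was 2.07-fold lower (log2 -1.05, with -1.03 in its other probe set). The autophagy and lysosome list had a median of -0.42 over 11 members, at percentile 0.26, and of -0.16 over 10 members with the median of each gene's probe sets. CTSL, WIPI1 and SQSTM1 were 2.34-, 2.29- and 2.10-fold lower, and GLA was 2.08-fold higher.

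In other lists the medians lay close to 0. The NRF2 list had a median of 0.04 over 16 members, which turned to -0.01 after loess removal, -0.03 after quantile normalization and -0.06 over 20 members with a floor of log2 1; HMOX1 was 1.87-fold lower, SLC7A11 at least 2.70-fold lower and GSR 1.70-fold higher. Glycolysis and hypoxia genes had a median of 0.10 over 23 members, with PKM 2.19-fold higher and VEGFA 1.99-fold lower, and the median ran from 0.08 to 0.26 over the alternatives. Cholesterol synthesis genes had a median of 0.08 over 15 members, with EBP 1.82-fold higher and STARD4 1.63-fold lower, and the median ran from -0.45 (without _s_at and _x_at probe sets) to 0.11. YAP and SRF target genes had a median of -0.03 over 9 members, with AJUBA 2.59-fold lower, and the median ran from -0.14 to 0.21 over the alternatives. The AHR and xenobiotic list had a median of -0.25, and fatty acid synthesis genes a median of 0.05, over 3 members each. With a floor of log2 1 the fatty acid median turned to -0.01 over 9 members, and the AHR median was -0.04 over 14 members with no floor. Oxidative phosphorylation genes had a median of 0.19 over 27 members, at percentile 95.4 (0.12 after quantile normalization), and ribosome biogenesis genes a median of 0.11 over 19 members. Ribosomal protein genes had a median of -0.01 over 23 members, and the sign turned under median centring and under quantile normalization (0.01 in both), with -0.10 after loess removal. In its brightest probe set RPL38 differed by 0.10 on the log2 scale, and in its other probe sets by 0.63 and 0.96. Reference housekeeping genes had a median of 0.13 over 11 members.

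The array controls differed little. The 18 hybridisation spike probe sets had a median log2 difference of -0.03, between -0.14 and 0.17. The ratio of 3′ to 5′ signal was 1.18 with analogue 3 and 1.21 with DMSO for GAPDH, and 10.0 and 11.8 for ACTB. For ACTB the 3′ signal thus lay far above the 5′ signal on both arrays, so the controls do not show that the RNA was intact.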

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

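All tests of explanations in this part were chosen only after the results were seen. Probe sets that the gene comparison left out, because the annotation gives them no gene or several, also held signal: of 909 at or above the floor on at least 1 array, 22 were at least 2-fold higher with analogue 3 and 20 were at least 2-fold lower. The higher ones are 2.42% of the 909, and no control array without treatment other than the single DMSO array exists to set a background.

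The first pattern weighed is that 5 cell cycle lists (checkpoint, kinetochore, spindle, G2/M and replication) were higher after a dose at which the compound is toxic to these cells. A trend of the difference with signal level could barely be tested. The sorted columns differed by at most 0.14 on the log2 scale as deposited, so trend removal had little to act on. The lowest of the 5 list medians was 1.10 after it, which shows only that a trend left in the deposited values was not the source. Accumulation of cells in G2 and mitosis as the whole cause was weighed by the replication list, whose median of 1.25 lay above 0. That median counts against this account only if replication transcripts stay level or fall in such cells. Whether they do was not tested, so the list cannot decide. Such accumulation could also add only to the higher level of mitotic genes. Replication-dependent histones had a median of -0.22 over 5 of 15 named members (0.06 over 9 with a floor of log2 1). With so few measured and a sign that turned, they do not decide the question. The G1 list pools cyclins and kinases with inhibitors, so its median of 0.04 over 9, at percentile 67.6, cannot decide it either. In it CDK2 (log2 at least 1.38), CCND3 (0.96), CCND1 (0.73), CDK6 (0.40) and CDK4 (0.04) lay above 0. CDKN1A (a bound of -0.83), CDKN1B (-0.17), RBL2 (-0.12) and RB1 (-0.04) lay below 0. Noise at low signal was not weighed for this pattern. With a floor of log2 7 the 5 medians lay between 0.45 (spindle) and 0.94 (kinetochore). Also open is a difference in growth state between the 2 single cultures, such as density or medium. Of the 112 measured genes of the 5 lists, 109 lay above 0. Treatment and dish predict this alike, so they cannot be told apart.

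The second pattern is that all measured genes of the ATF4 and interferon lists were lower with analogue 3. A difference in RNA quality between the arrays is argued against, since the 3′ to 5′ ratios of the control probe sets differed by at most 0.241 on the log2 scale. This leaves aside a loss of quality shared by both arrays. Noise at low signal was weighed by the medians with a floor of log2 7. These were -0.979 over 11 ATF4 genes (SD 0.733) and -0.902 over 11 interferon genes (SD 0.661). Both lists met the rule for this, set after the results were seen, only narrowly. Most of these genes reached that floor on the DMSO array alone and so could only be lower, hence the medians cannot decide. Members at or above log2 7 on both arrays were all lower. These were PSAT1 (log2 -1.83), ATF4 (-1.09), CEBPB (-0.98) and MTHFD2 (-0.76), and IFIT1 (-1.79), ISG15 (-1.46) and IFI6 (-1.18). For these genes alone, low signal is argued against. Leukocyte RNA in the DMSO sample is argued against by its markers, the highest of which was LCP1 at 1.25 times the array median. Growth state of the single cultures remains open (34 of 34 genes lower, under either account), for instance amino acid shortage in a denser DMSO dish. Exchanged array labels also remain open: all 310 calls would turn sign, and no transcript in the table independently marks the treated array.

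The third pattern is that heat shock chaperone genes were higher. A shared response with NRF2 targets, which reactive compounds often induce together with heat shock genes, is argued against by the NRF2 list median of 0.041, and folding stress of the endoplasmic reticulum as well by a median of -0.210. A response of the chaperone genes to the compound, or a link of these genes with growth, may account for it, and neither was tested.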

How the results depend on the processing

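No paired analysis was possible because each group holds 1 array; for the same reason no replicate could be left out. Higher genes (175) numbered 176 after loess removal, and moved to 43 with a floor of log2 7, 475 with no floor, 113 without _s_at and _x_at probe sets, 477 at 1.5-fold and 29 at 3-fold. Lower genes (135) moved to 217 with a floor of log2 4, 38 with log2 7, 724 with no floor, 81 with the median of a gene's probe sets, 89 without _s_at and _x_at probe sets, 461 at 1.5-fold and 34 at 3-fold. Floors added after seeing the data gave 419 higher and 586 lower at log2 1, and 319 and 334 at log2 3, among 11158 and 8523 genes; all 175 and 135 genes were among them. The share of calls that were higher was 56.5%, against 39.6% with no floor and 41.7% at log2 1, so the excess of increases depends on the floor. No scaling moved the median of all genes by over 0.1. The 8 leading lists kept their sign in every alternative. With a floor of log2 7, which raises more values to the floor and so shrinks differences, medians were 0.52 (checkpoint), 0.94 (kinetochore), 0.45 (spindle), 0.90 (G2/M), 0.81 (replication), -0.98 (ATF4), -0.90 (interferon) and 0.65 (heat shock). With no floor they were 1.66 (replication), -1.85 (ATF4) and -1.74 (interferon); at log2 1, 1.31 (kinetochore), 1.66 (replication) and -1.88 (ATF4); at log2 3, 1.51 (replication) and -1.27 (interferon). The median of a gene's probe sets gave 1.02 (G2/M) and -1.17 (interferon); leaving out _s_at and _x_at probe sets gave -1.09 (ATF4), 0.47 (heat shock, 3 genes) and -1.14 (interferon). The cause was not tested for these. Histone genes reversed from -0.22 to 0.0593 at log2 1, where 9 members in place of 5 were measured. Over all 33 lists, 269 medians under alternatives moved by less than their bootstrap SD and 51 by more. Of the values of 151 named genes under alternatives, 1193 moved by less than the SD of 1 probe set and 176 by more. This tally is no measure of stability, because many values could hardly move. Centring, loess removal and quantile normalization each left all 151 within that SD. Lower floors cannot change genes above the floor on both arrays. With the median of their probe sets HNRNPA2B1 turned from 0.87 to -0.05, SCD from -0.44 to 0.18 and RPS9 from -0.11 to 0.05. NQO1, at -0.01, turned to just above 0 when centred. Low signal limits what can be said: the correlation across genes between probe sets of 1 gene was r = 0.55 where the dimmer lay at log2 1 to 3, and 0.93 above log2 7.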

Other observations

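The lists in this part were drawn up after the gene values had been seen. Cytosolic aminoacyl-tRNA synthetases, which load amino acids onto tRNAs, had a median of -0.84 over 17 members. Of these, 7 were at least 2-fold lower with analogue 3: SARS1 (log2 -1.62), GARS1 (-1.50), CARS1 (-1.26), WARS1 (-1.24), AARS1 (-1.20), YARS1 (-1.17) and IARS1 (-1.14). TARS1, EPRS1, NARS1 and LARS1 lay between -0.87 and -0.49, and RARS1, FARSA, KARS1, HARS1, VARS1 and FARSB between 0.10 and 0.45. The 7 measured mitochondrial synthetases all lay above 0, with a median of 0.17. Amino acid transporters had a median of -1.47 over 8 members, with SLC38A1 at 146.7 against 503.9, SLC3A2 at 38.4 against 126.4 and SLC7A1 at 117.9 against 336.2.

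Genes of class I antigen presentation, many of them inducible by interferon, were all lower, with a median of -0.67 over 10 members. TAP1 and HLA-E were lower by 1.15 and 1.01 on the log2 scale, HLA-B by 0.82 and B2M by 0.40. The 7 measured subunits of the cytosolic chaperonin CCT, which folds tubulin and actin, were all higher, between 0.32 (CCT5) and 0.78 (CCT6A). Of a list of 10 BMP signalling targets, only 3 were measured. In it ID1 was higher by 1.56 and ID3 by 1.97, while HEY1 differed by -0.23. So few members cannot show whether BMP signalling differed.

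Some genes under the floor on both arrays, chosen after their values were seen, also differed. POLE2 was 27.5 with analogue 3 and 5.23 with DMSO, CDC25A 21.5 and 4.82, and FAM111B 24.1 and 3.71. RSAD2 was 2.82 and 31.7, ATF3 2.97 and 24.9, CHAC1 3.48 and 22.7, and GDF15 0.628 and 19.2.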
